A study of Mus musculus with 12 samples.

How the data were processed

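Messenger RNA was measured by RNA sequencing in mouse CD4+ T cells taken from spleen and peripheral lymph nodes of C57BL/6 mice, activated, and cultured with interleukin 6 and an inhibitor of the TGF-β receptor. Per the labels, cells were wild type (WT) or carried the floxed Smad4 allele together with a Cre recombinase driven by Cd4 (KO), and were collected 3 h or 12 h after treatment, with 3 libraries in each of the 4 groups. RNA was extracted with Trizol and cleaned on an RNeasy column, and libraries were made with the TruSeq kit, version V2, and sequenced on an Illumina HiSeq instrument, per the labels' protocols. The series also describes unpolarised cells and a time point before treatment, which were not analysed here.

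The deposited table holds log2 expression values that the authors normalised for depth, with 24538 gene rows and 12 library columns. Trim Galore, STAR, featureCounts and DESeq2 and the build mm10 are named in the submitters' processing notes, and their versions, options and gene annotation are not given in the sources used here. The labels call the values log2 normalized without naming the transform. Their form is that of a regularised log: 5663 rows were at exactly 0 in all 12 libraries, 0 rows were at 0 in only some, 3989 rows had a negative mean, and values ran from -2.37 to 20.1. Such a transform pulls the values of genes with few reads together, so differences of low genes are understated and no raw count can be recovered. The depth of each library is therefore unknown, no counting interval or detection floor was computed, and precision was taken from the spread between the 3 libraries of a group. Fold values are 2 to the power of a difference of these deposited log2 values. All 12 columns matched 1 sample title each, and 0 columns of per-sample values were left unmapped. A spreadsheet had turned 26 row names into dates, 2 of which named 2 rows each; 19 of these rows passed the filter and were tested, and none was named. The TruSeq kit of this version does not mark strand, so reads from overlapping or antisense genes could not be told apart.

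Differences were computed in R 4.3.3 with limma 3.58.1. A mean was fitted for each of the 4 groups over all 12 libraries (lmFit), so that all groups shared 1 estimate of the spread, and contrasts were tested two-sided with a moderated statistic whose prior followed the mean level (eBayes with trend). The contrasts were KO against WT at 3 h, KO against WT at 12 h, the mean of these 2 differences, the difference between them, and 12 h against 3 h within each genotype. Genes with a mean deposited value of at least 3 over the 12 libraries were kept, which left 12436 genes. Adjusted p-values are Benjamini-Hochberg values over these genes, and a gene was called at an adjusted p under 0.05. Errors given with a log2 difference are standard errors (SE) from this model, and errors given with a group mean are standard deviations (SD) of 3 libraries.

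Groups, tests, 24 gene lists, the rule for named genes and the alternatives other than those named as added later were set before the data were examined. The named genes were taken from fixed genes, among them Smad4, Ski and Skil; the 8 largest rises and 8 largest falls in each genotype comparison among called genes whose KO and WT values did not overlap and whose higher group mean was at least 5; the 6 largest of each kind for the change with time; and up to 4 members of each list, called members first. Some genes that meet this rule are not reported here, and counts include them. Gene models without a proper name and receptor gene segments were counted and not named. Chance alone separates all values of 3 libraries from those of 3 others in 10% of genes.

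The lists were the TH17 programme, IL-6 and STAT3 responsive genes, TGF-β and SMAD target genes, SMAD and TGF-β pathway components, TH1 genes, TH2 genes, regulatory T cell genes, follicular helper T cell genes, early T cell activation genes, naive and resting T cell genes, cell cycle genes, MYC and ribosome biogenesis genes, glycolysis genes, oxidative phosphorylation genes, cholesterol synthesis genes, type I interferon response genes, unfolded protein and amino acid stress genes, heat shock genes, mitochondrially encoded genes, and markers of B cells, of CD8 T and NK cells, of gamma-delta T and NKT cells, of myeloid and dendritic cells, and of erythroid cells and platelets. The 21 lists with at least 5 kept genes were tested with camera from limma, which asks whether the members of a list moved more in 1 direction than the other genes, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison. Smad4 was left out of the list tests. The tests were repeated with a correlation estimated from the residuals and with fry, a test of a list on its own. For each list the members were also adjusted over the list alone.

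The replicate numbers of the labels were used as a block in an alternative. Whether they pair the libraries was checked from the correlation of same-numbered libraries' deviations from their group means: it was 0.194, 0.402 and 0.347 for KO and WT at 3 h, 0.174, 0.500 and 0.186 at 12 h, and 0.211, 0.432 and 0.207 for WT at both times, all above the 0.1 set as the limit. The KO libraries at both times did not meet it. Without the sex-linked genes the pairs at 3 h came to 0.111, 0.116 and 0.269. Those at 12 h came to 0.0764, 0.187 and 0.0683, and those of WT at both times to 0.132, 0.112 and 0.0851. The pairing thus comes from the data, since the labels do not say what a number stands for. The replicates are numbered samples, with nothing in the labels stating that they came from separate animals, so p-values measure the spread between these samples. Replicate 2 differed from the others in sex-linked transcripts.

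Other alternatives were eBayes without trend, robust eBayes, array weights, no filter on low values (18875 genes), a minimum mean of 5 (10935 genes), quantile normalization, centring of each library on its median, a fit on the compared groups alone, and leaving out each library in turn. Leaving out all 4 libraries of replicate 2, and the block combined with array weights or with each library left out, were added after the data had been seen. Where these moved a count by at least 1.5 times, the closing section gives the value. The method was tested on simulated data for KO against WT at 3 h over 12436 genes: it recovered 52.2% of 67 genes changed by a log2 value of 0.5, 88.1% of 67 changed by 1, and 100% of 66 changed by 2, and of 172 calls 7 were unchanged genes (4.07%). This was 1 run, with noise drawn separately for each gene and library. It held no correlation between genes or between libraries of the same number, so its rates need not hold for the real libraries. Positions were looked up in GENCODE vM21 on GRCm38, the assembly that mm10 stands for, where 97.7% of the 12436 kept genes had 1 position. No 2 libraries held identical values.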

Results

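The series addresses how SKI and SMAD4 hold back the differentiation of TH17 cells, the helper T cells that make interleukin 17 (IL-17). SMAD4 is the shared partner of the receptor-regulated SMAD proteins that carry TGF-β and BMP signals to the nucleus, and SKI is a corepressor that binds SMAD proteins. The 12 libraries came from CD4+ T cells cultured with interleukin 6 (IL-6) while the TGF-β receptor was inhibited. There were 3 WT and 3 KO libraries at 3 h, and 3 WT and 3 KO libraries at 12 h. Values are the deposited log2 values, whose read depth is unknown. The first principal component carried 80.9% of the variance of the 12 libraries and separated the times.

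Smad4, the gene the KO cells were bred to lose, lies on chromosome 18 at 73639009 to 73703780 (GRCm38, minus strand). Its level in WT was 11.65, 11.58 and 11.71 at 3 h and 11.53, 11.49 and 11.52 at 12 h. In the KO libraries it was 11.66, 11.62 and 11.66 at 3 h and 11.50, 11.50 and 11.60 at 12 h. The difference was 0.00 ± 0.06 (SE, n = 3 per group) at 3 h and 0.02 ± 0.06 at 12 h (limma adjusted p = 0.993 and 1.00). A floxed allele loses part of a gene, and a value over the whole gene model can keep the reads of the rest, so this value does not check the genotype labels. The groups are therefore called KO-labelled below, and every direction given for them rests on the labels. Ski, on chromosome 4 at 155154075 to 155222592, was also at like levels, with a difference of -0.00 ± 0.06 at 3 h and 0.05 ± 0.06 at 12 h (adjusted p = 0.995 and 1.00). The labels state female mice, yet the 4 replicate 2 libraries, 1 in each group, held Xist at no more than 5.70 and Ddx3y, a Y-linked gene, at no less than 12.3, against at least 15.1 and at most 2.77 in the 8 others.

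At 3 h, 5 of 29 TGF-β and SMAD target genes and 3 of 23 SMAD pathway components were called higher in the KO-labelled libraries. Ccr8, a chemokine receptor (chromosome 9, 120092114 to 120094906), rose by 1.37 ± 0.10 (SE, n = 3 per group), or 2.59-fold (limma adjusted p = 3.01e-06). Ccl1, the chemokine that binds it, rose by 1.72 ± 0.34 (0.0288). Skil, which encodes the SKI-related corepressor SnoN (chromosome 3, 31095058 to 31122577), rose by 0.99 ± 0.09, or 1.98-fold (0.000137). Pmepa1, a TGF-β-induced feedback inhibitor of SMAD signalling (chromosome 2, 173224458 to 173276533), rose by 0.60 ± 0.07 (0.00105). Among the TGF-β and SMAD target genes 5 of 29 rose, 0 fell and 24 were not called, with 9 higher and 1 lower when adjusted over the list alone. The other 2 risers were Smad3, a receptor-regulated SMAD (0.32 ± 0.06, 0.0198), and Bhlhe40, a helix-loop-helix repressor (0.26 ± 0.05, 0.0353). The list as a whole was higher (camera adjusted p = 6.57e-08, median 0.14) and held with an estimated correlation (adjusted p = 0.0296), the 1 list at 3 h that did. The SMAD and TGF-β pathway components were higher too (camera adjusted p = 0.000158, and adjusted p = 0.202 with an estimated correlation). Their 3 called members, the same number when adjusted over the list alone, were Skil, Smad3 and Bmpr2, the type II BMP receptor (0.82 ± 0.14, 0.0160). Skil and Smad3 belong to both lists, as do Ski, Smad6, Smad7, Smurf1, Smurf2, Tgfbr1 and Tgfbr3, so the lists are not independent of each other. Further large rises were in Ddr1, a collagen receptor kinase (2.23 ± 0.44, 0.0292), Setbp1 (1.26 ± 0.20, 0.00991) and Adamts6, a secreted metalloprotease (0.72 ± 0.12, 0.0114).

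Larger falls at 3 h included 4 of 26 naive and resting T cell genes and 2 of 21 TH1 genes. S1pr1, the sphingosine receptor that guides T cells out of lymphoid organs (chromosome 3, 115710433 to 115715072), fell by 2.39 ± 0.42 on the log2 scale, or 5.22-fold, from 10.19 ± 1.10 to 7.80 ± 0.30 (SD, n = 3; limma adjusted p = 0.0160). Klf3, a zinc finger repressor, fell by 1.07 ± 0.21 (0.0288). Txnip, an inhibitor of thioredoxin and of glucose uptake, fell by 1.06 ± 0.22 (0.0321). They were among the 4 of 26 naive and resting T cell genes that fell. In this list 0 rose, and 10 were lower and 1 higher when adjusted over the list alone. That list was lower in camera (adjusted p = 5.10e-08, median -0.26), but not with an estimated correlation (adjusted p = 0.223) or in fry (0.114). The 16 B cell markers moved the same way (adjusted p = 0.000347, median -0.26; adjusted p = 0.296 with an estimated correlation). Of them limma called 0 over all genes, 0 when adjusted over the list alone, and 0 with the replicate block. Of 21 TH1 genes 2 fell, Il18r1 (-2.21 ± 0.48, 0.0398) and Il12rb2 (-1.12 ± 0.25, 0.0438), which encode receptor chains for IL-18 and IL-12. Of the 12 fits that leave out 1 library 8 ended the call of Il18r1 and 10 that of Il12rb2, with adjusted p up to 0.181 and 0.194. Adjusted over the list alone 5 TH1 genes were lower. None had a positive difference, and the median was -0.32 (camera adjusted p = 5.17e-09; adjusted p = 0.129 with an estimated correlation, and 0.00868 with the replicate block as well). The remaining large falls were Lgmn, a lysosomal protease (-2.16 ± 0.33), Rflnb, a filamin-binding protein (-2.06 ± 0.40), and Ccr2, a chemokine receptor (-2.03 ± 0.37). Next were Bambi-ps1 (-2.00 ± 0.41), Myo6, a myosin (-1.90 ± 0.34), Ypel3 (-1.83 ± 0.32) and Smpdl3a (-1.83 ± 0.28). The adjusted p of these 7 genes ran from 0.00709 to 0.0340. Bambi-ps1 is annotated as a processed pseudogene that can share reads with its parent, so its value is uncertain.

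In the other lists at 3 h few members moved. TH17 genes had 2 of 18 called higher, among them Rbpj, the DNA-binding partner of Notch (0.30 ± 0.07, 0.0477), 3 when adjusted over the list alone, and no list call (adjusted p = 0.235). Their median was -0.01 while their mean was 0.08 and the test pointed up. The call of Rbpj was weak. It ended when any 1 library of the 3 h groups or of WT at 12 h was left out, and with quantile normalization or median centring. IL-6 and STAT3 responsive genes were lower (adjusted p = 0.0461; adjusted p = 0.565 with an estimated correlation). Of 22 members 2 were called, the interferon gamma receptor chain Ifngr1 (-1.35 ± 0.28, 0.0319) and the kinase Pim2 (-0.61 ± 0.13, 0.0389), and 3 lower when adjusted over the list alone. Type I interferon response genes were lower (0.00163; adjusted p = 0.632 with an estimated correlation). The interferon-induced GTPases Gbp2 (-1.73 ± 0.27, 0.00709) and Gbp3 (-0.99 ± 0.21, 0.0362) were the 2 of 33 called, and 3 lower when adjusted over the list alone. Cholesterol synthesis (0.00342), glycolysis (0.0102) and MYC and ribosome biogenesis genes (0.0235) were lower in camera with 0 members called by limma and medians of -0.08, -0.04 and -0.05. With an estimated correlation they had adjusted p = 0.592, 0.508 and 0.686. When adjusted over the list alone 1 glycolysis gene, Pdk1, was lower and 0 in the others. Not called were regulatory T cell genes (adjusted p = 0.235; Ccr8 higher, 7 higher and 5 lower when adjusted over the list alone), and TH2 genes (0.538; Ccr8 higher, 2 and 4). Early T cell activation genes were not called either (0.538; 3 and 3), though Tnfaip3, an inhibitor of NF-κB signalling, fell by 0.34 ± 0.08 (adjusted p = 0.0456). The same held for follicular helper genes (0.587; 2 and 3), heat shock genes (0.243; 0 and 2) and CD8 T and NK cell markers (0.727; 2 and 1). Oxidative phosphorylation (0.431), unfolded protein (0.236), cell cycle (0.587) and myeloid genes (0.587) were not called and had 0 in either direction when adjusted over the list alone. For the CD8 T and NK cell markers the median was -0.29 and the mean -0.03. For the cell cycle genes the median was 0.01 and the mean -0.00. For TH2 genes camera pointed down and fry up. The call of Tnfaip3 also ended when any 1 of the KO-labelled 3 h libraries was left out.

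In all, limma called 130 genes at 3 h, 37 higher and 93 lower, of which 5 rose and 45 fell at least 2-fold. In all 1131 genes had an unadjusted p under 0.05. This count rested strongly on the settings. It was 9 without the trend in the prior, 14 without the filter on low values, 32 in a fit on the compared groups alone, 54 with array weights and 200 with the replicate block. The blocked count was itself 44, 59, 73, 176 and 141 without KO 3 h replicate 1, WT 3 h replicates 1 and 3 and KO 3 h replicates 2 and 3, and 183 with array weights, alternatives chosen after seeing the data. The excess of falls also rested on the settings. Without the trend 7 genes were higher and 2 lower, without the filter 12 and 2, on the compared groups 17 and 15, and with array weights 27 and 27. It was 21 and 15, 18 and 15, and 12 and 10 without WT 3 h replicates 1 and 3 and KO 3 h replicate 1, and 27 and 31 without KO 3 h replicate 2. Falls stayed in excess with the replicate block (56 and 144), without WT 3 h replicate 2 (36 and 225) and without the 4 replicate 2 libraries (16 and 101), among others. Leaving out 1 library gave 36, 261 and 33 calls for WT 3 h replicates 1, 2 and 3, and 22, 58 and 77 for KO 3 h replicates 1, 2 and 3. It gave 71 and 83 for WT 12 h replicates 2 and 3, and 66 for KO 12 h replicate 2. Of the 29 named calls 4, with Skil, Ccr8 and Pmepa1 among them, were kept under each alternative, while the other 25 were lost under at least 1. Without the trend 25 of the 29 were lost, and without the filter 25, Smad3, Bmpr2 and Gbp2 among them in both. On the compared groups alone 18 were lost, and with array weights 15. Without KO 3 h replicate 1, 20 of the 29 were lost, S1pr1 among them (adjusted p = 0.0839, range over its 22 alternatives 0.000401 to 0.182). Without WT 3 h replicates 1, 2 and 3 it was 18, 1 and 19, with S1pr1 at 0.0509 for the last. Without KO 3 h replicates 2 and 3 it was 15 and 9. Leaving out WT 12 h replicates 1, 2 and 3 ended 2, 7 and 5 of these calls, and leaving out KO 12 h replicates 1, 2 and 3 ended 4, 9 and 1. Among the list calls, B cell markers had adjusted p = 0.0560 without KO 3 h replicate 1. The interferon list had 0.164, 0.217 and 0.122 without KO 3 h replicates 1 and 2 and WT 3 h replicate 3. IL-6 and STAT3 genes stood at 0.502 and 0.153 without KO 3 h replicate 1 and WT 3 h replicate 2. The MYC list stood at 0.130, 0.179 and 0.562 without KO 3 h replicates 1 and 3 and WT 3 h replicate 2. Cholesterol genes were at 0.274 and 0.179 without WT 3 h replicate 2 and KO 3 h replicate 3, and glycolysis genes at 0.257 without WT 3 h replicate 2. With the replicate block, which pairs the libraries at 3 h, Il12rb1, Il3, Tcf7, Nfkbiz, Igtp and Hspa1a were lower and Il2ra and Xcl1 higher (blocked adjusted p = 0.0208, 0.0316, 0.0483, 0.0461, 0.0483, 0.0475, 0.0410 and 0.00563).

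**Figure D1:**
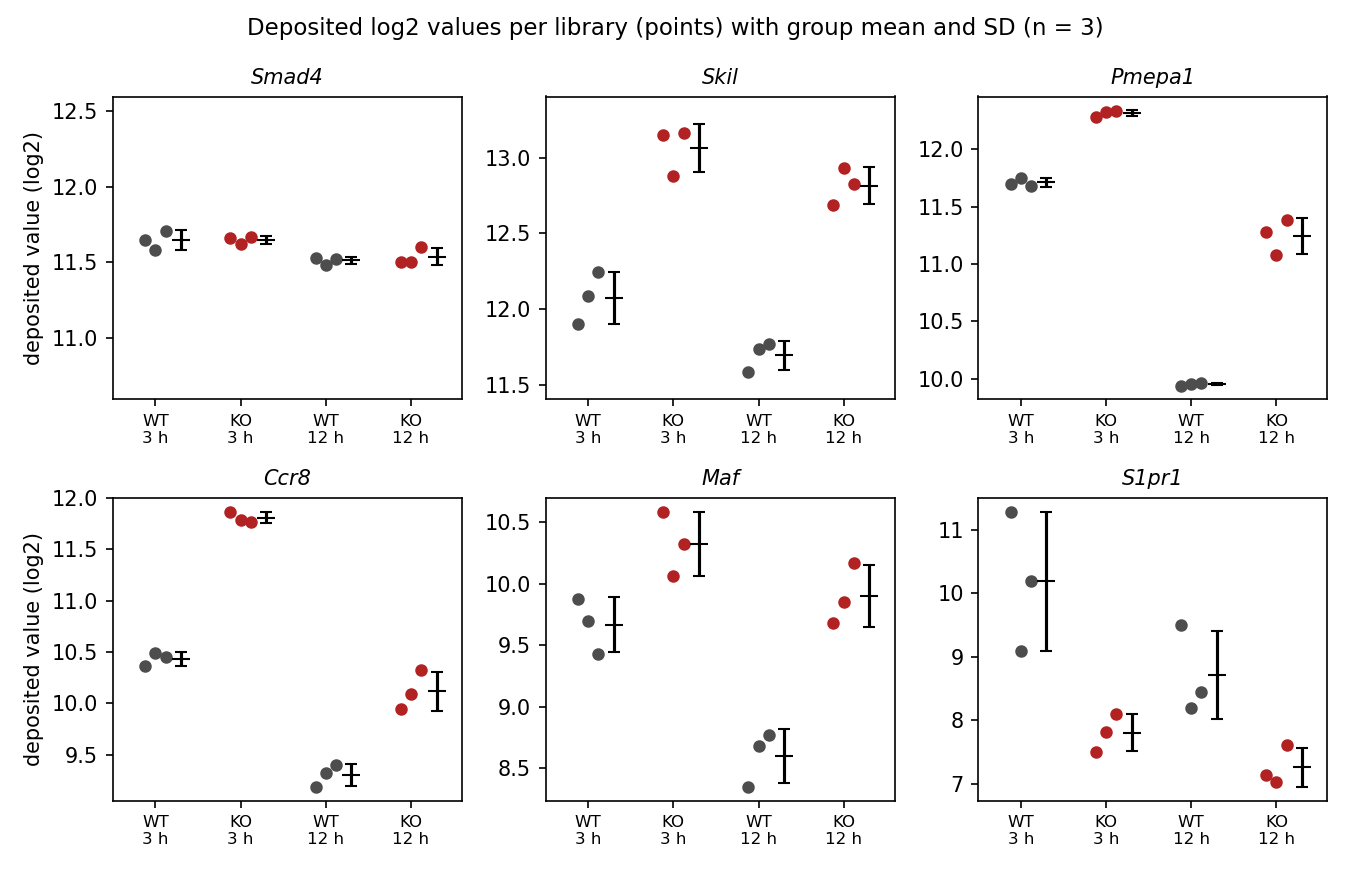
Deposited log2 values (vertical axis, range differing by panel) of 6 genes in the 12 libraries, by genotype label and time (horizontal axis); points are libraries, and bars beside them are the group mean and SD (n = 3). Smad4 is level across the groups, Skil, Pmepa1 and Ccr8 are higher in each KO-labelled library than in each WT library of the same time, and S1pr1 has lower means, called at 3 h but not at 12 h (adjusted p = 0.201).

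At 12 h the genes of the TH17 programme stood higher in the KO-labelled libraries. Maf and Rora, transcription factors of TH17 cells (chromosome 8, 115682942 to 115707794, and chromosome 9, 68653786 to 69388246), rose by 1.30 ± 0.16 (SE, n = 3 per group; limma adjusted p = 0.000672) and 1.16 ± 0.18 (0.00347). Ahr, the aryl hydrocarbon receptor (chromosome 12, 35497974 to 35535038), rose by 1.32 ± 0.19 (0.00222). With Rbpj (0.38 ± 0.07) they were among the 5 of 18 TH17 genes that rose, and 0 fell. Of the list 7 were higher when adjusted over the list alone. The list was higher as a whole (camera adjusted p = 1.05e-16, median 0.29, 16 of 18 members positive) and held with an estimated correlation (adjusted p = 0.00132). Il17f, which encodes an IL-17 cytokine, was at 2.34 in WT and 3.07 in KO-labelled libraries, near the low end of the scale, and was not called (0.73 ± 0.23, adjusted p = 0.259).

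TGF-β and SMAD target genes were higher at 12 h as well, with 9 of 29 called higher, 0 lower, and 12 higher and 1 lower when adjusted over the list alone. Pmepa1 rose by 1.30 ± 0.07, or 2.45-fold (limma adjusted p = 6.10e-08), and Skil by 1.12 ± 0.09, or 2.17-fold (1.63e-05). Smad3 rose by 0.67 ± 0.06 (2.13e-05), Id2, a helix-loop-helix inhibitor of DNA binding, by 0.85 ± 0.09 (0.000119), and Ccr8 by 0.81 ± 0.10 (0.000338). This list also held with an estimated correlation (camera adjusted p = 2.59e-19; adjusted p = 0.00115 with an estimated correlation). Skil and Smad3, which belong to both lists, were the 2 of 23 SMAD and TGF-β pathway components that rose, 4 when adjusted over the list alone (camera adjusted p = 2.62e-05, and adjusted p = 0.103 with an estimated correlation). Further large rises were in Nt5e, the ectoenzyme CD73 that makes adenosine (chromosome 9, 88327197 to 88372092; 1.69 ± 0.28, 3.23-fold, 0.00724), and Ccl1 (1.69 ± 0.34, 0.0275). The next were in the chemokine gene Xcl1 (1.48 ± 0.29, 0.0252), Gadd45g, a stress-response gene (1.38 ± 0.20, 0.00244), and Mical1, an actin-modifying oxidoreductase (1.33 ± 0.14, 0.000119). The largest falls were in Itgb3, the integrin beta 3 chain (chromosome 11, 104608000 to 104670476; -1.64 ± 0.26, 3.12-fold, 0.00505), Icosl, the ligand of ICOS (-1.21 ± 0.24, 0.0275), and St8sia4, a polysialyltransferase (-1.06 ± 0.23, 0.0497). Smaller falls were in Dnah8, an axonemal dynein (-1.02 ± 0.18, 0.0120), Gimap7, a lymphocyte GTPase (-0.83 ± 0.16, 0.0175), Syne2, a nuclear envelope protein (-0.82 ± 0.15, 0.0140), and Cd226, a costimulatory receptor (-0.73 ± 0.13, 0.0105).

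Several other lists passed camera at 12 h with few called members, and none of those in this paragraph held with an estimated correlation. IL-6 and STAT3 responsive genes were higher (adjusted p = 0.000523; adjusted p = 0.157 with an estimated correlation). Gadd45g and Cish, an inhibitor of cytokine signalling (0.44 ± 0.07, 0.00678), were called among 22 and 5 higher when adjusted over the list alone. Regulatory T cell genes (0.000328; adjusted p = 0.157 with an estimated correlation) had Ccr8 and Nt5e higher among 20, and 4 when adjusted over the list alone. Follicular helper genes (0.0273; adjusted p = 0.139 with an estimated correlation) had Maf and Pdcd1, the receptor PD-1 (0.44 ± 0.07, 0.00401), higher among 17, and 5 higher and 2 lower when adjusted over the list alone. TH1 genes were lower (6.20e-05; adjusted p = 0.157 with an estimated correlation, and 0.0251 with the replicate block as well). Limma called 0 of 21, and 2 were lower when adjusted over the list alone. The 37 cell cycle genes were lower, with a median of -0.15 (4.11e-07; adjusted p = 0.103 with an estimated correlation, and 0.0338 with the replicate block as well). Limma called 0 of them over all genes and 0 when adjusted over the list alone. Naive and resting genes were lower (0.00195; adjusted p = 0.425 with an estimated correlation), with 1 of 26 called lower and 1 higher and 4 lower when adjusted over the list alone. B cell markers again moved with them (0.00507; adjusted p = 0.350 with an estimated correlation; median -0.23), with 0 called in either way. Cholesterol synthesis genes were higher (0.00507), and heat shock (0.00507), MYC (0.0241) and type I interferon genes (0.0417) lower, with 0 members called over all genes and 1 interferon gene lower when adjusted over the list alone. With an estimated correlation they had adjusted p = 0.486, 0.486, 0.612 and 0.662. Not called were TH2 genes (adjusted p = 0.514; Ccr8 higher, 1 higher and 2 lower when adjusted over the list alone) and CD8 T and NK cell markers (0.261; Xcl1 higher, 1 and 0). Early activation genes were not called (0.699; 6 and 5), though Irf8, an interferon regulatory factor, rose by 0.86 ± 0.12 (adjusted p = 0.00222). Glycolysis (0.275), oxidative phosphorylation (0.166), unfolded protein (0.0581) and myeloid genes (0.813), each with 0, were not called. For early activation genes the median was -0.02, the mean 0.01 and the test pointed up.

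Limma called 83 genes at 12 h, 62 higher and 21 lower, of which 14 rose and 6 fell at least 2-fold. In all 792 genes had an unadjusted p under 0.05. The count was 39 without the trend, 40 without the filter and 167 with array weights. It was 114 with the replicate block, and then 226 with array weights as well and 50 to 143 with 1 library left out, alternatives chosen after seeing the data. It was 22 without the 4 replicate 2 libraries, which also leaves fewer samples. Leaving out WT 12 h replicate 1 gave 49 and KO 12 h replicate 1 gave 53. Of the 26 named calls 8, with Skil, Pmepa1, Smad3, Ccr8, Id2, Mical1 and Maf among them, were kept under each alternative. Without the trend, the filter and the 4 replicate 2 libraries 12, 14 and 14 of the 26 were lost, with Rora and Cish among them each time. Ahr was lost without the replicate 2 libraries. Leaving out WT 12 h replicates 1, 2 and 3 ended 7, 8 and 5 of the 26, and leaving out KO 12 h replicates 1, 2 and 3 ended 9, 7 and 5. Each of these but KO 12 h replicate 3 ended the call of St8sia4, at adjusted p = 0.198, 0.114, 0.155, 0.257 and 0.178 in that order (range over its 22 alternatives 0.0113 to 0.401). Leaving out a 3 h library ended at most 2 named calls. St8sia4 was among them for KO 3 h replicates 1, 2 and 3 and WT 3 h replicate 2 (0.0643, 0.0512, 0.0622 and 0.0596), and WT 3 h replicate 3 ended 1 other. Without WT 12 h replicate 1 the naive, follicular helper, cholesterol and B cell lists had adjusted p = 0.0644, 0.0644, 0.477 and 0.225. Without KO 12 h replicate 3 the regulatory, follicular helper, cholesterol and heat shock lists had 0.0767, 0.193, 0.0901 and 0.0617. The heat shock list had 0.0817 without WT 12 h replicate 2, and the follicular helper list 0.0559 without WT 3 h replicate 1. For the MYC list it was 0.408, 0.128, 0.102 and 0.0911 without WT 12 h replicates 2 and 3 and KO 12 h replicates 2 and 3. For the interferon list it was 0.373, 0.407, 0.284 and 0.0515 without WT 12 h replicate 3, KO 12 h replicates 1 and 2 and WT 3 h replicate 1. With the replicate block Il6ra was higher and Gzmb, Il3 and Oas3 were lower (blocked adjusted p = 0.0249, 0.00559, 0.0469 and 0.0230). For replicates 1 and 3 the pairing at 12 h fell below the limit of 0.1 without the sex-linked genes (0.0764 and 0.0683).

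**Figure D2:**
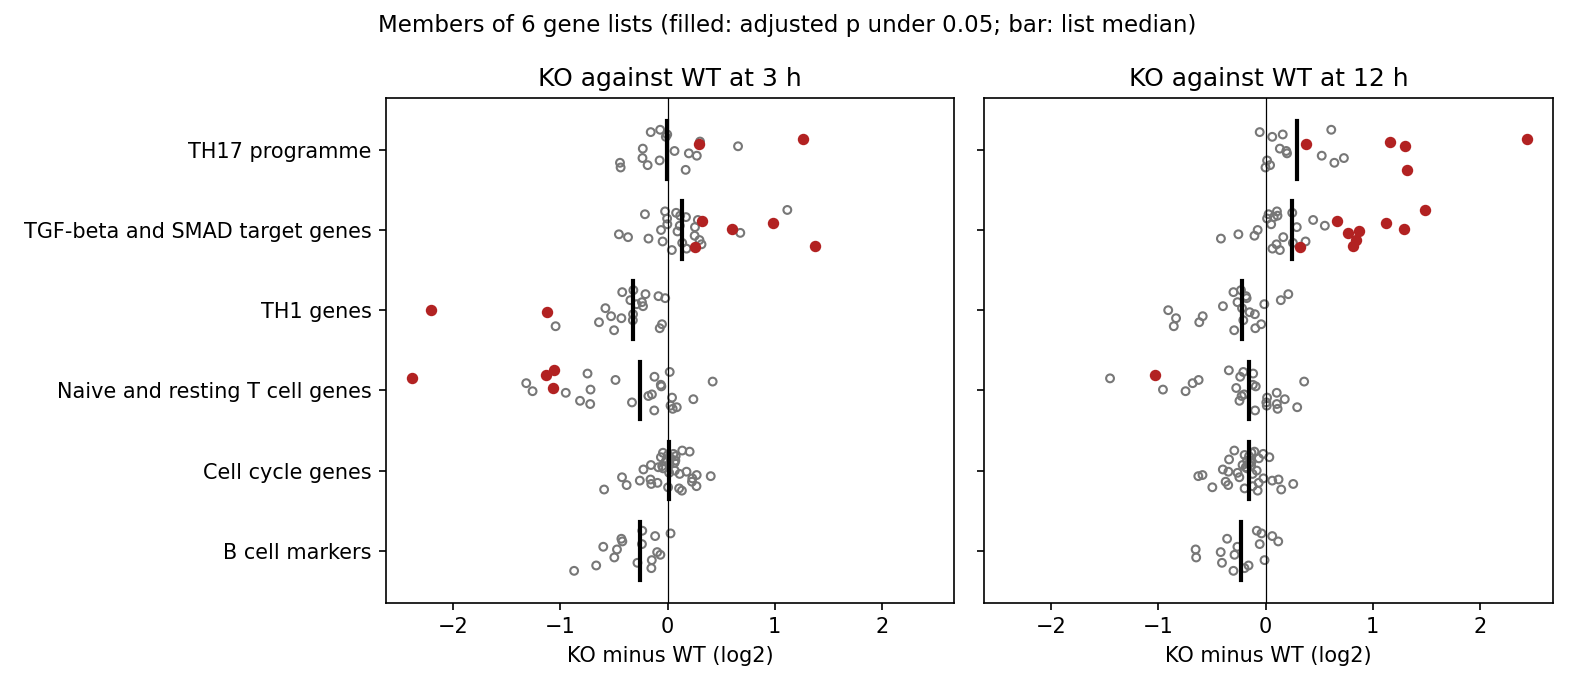
Log2 difference of KO-labelled minus WT libraries (horizontal axis) for the kept members of 6 gene lists (vertical axis) at 3 h and 12 h; circles are genes, filled where the adjusted p was under 0.05, and the bar is the list median. The TH17 list has its median at -0.01 at 3 h and 0.29 at 12 h, and that of the TGF-β and SMAD target genes is 0.14 and 0.25.

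Averaged over both times, which uses all 12 libraries, limma called 285 genes, 128 higher and 157 lower, with 1334 at an unadjusted p under 0.05. The fit takes the 12 libraries as independent samples. Same-numbered WT libraries deviated alike at both times (0.211, 0.432 and 0.207), the KO-labelled ones less so (0.0637, 0.368 and 0.0892). If a number stands for the same animals, there are fewer independent samples than libraries, and the p-values of this average may be too small. The replicate block does not model animals within a genotype. Ccr8 was higher by 1.09 ± 0.07 (SE; limma adjusted p = 1.77e-07), Skil by 1.05 ± 0.07 (2.05e-07) and Pmepa1 by 0.95 ± 0.05 (3.61e-08). TGF-β and SMAD target genes had 10 of 29 called higher and 0 lower, 12 and 2 when adjusted over the list alone (camera adjusted p = 2.97e-15; adjusted p = 0.00269 with an estimated correlation). TH17 genes had 5 of 18 called higher, the same number when adjusted over the list alone (1.14e-07; adjusted p = 0.0211 with an estimated correlation, and 0.0674 with the replicate block as well). Of the naive and resting genes 6 fell and 1 rose, with S1pr1 at -1.92 ± 0.29 (0.00204). Of the list 14 were lower and 2 higher when adjusted over the list alone (1.14e-07; adjusted p = 0.189 with an estimated correlation). Il10, Il3 and Csf2, which encode cytokines of helper T cells, were lower by -1.07 ± 0.23, -0.71 ± 0.16 and -0.73 ± 0.17 (0.0251, 0.0269 and 0.0296). The count was 128 without the trend (77 higher, 51 lower), 92 without the filter (65 and 27) and 163 without the replicate 2 libraries (60 and 103). More genes were higher than lower also without WT 3 h replicates 1 and 3 (108 and 106, 102 and 79), KO 3 h replicates 1 and 2 (92 and 67, 127 and 114), WT 12 h replicates 1 and 3 (98 and 67, 101 and 86) and KO 12 h replicates 1 and 2 (89 and 66, 125 and 81), so the balance of rises and falls rested on the settings. Without WT 3 h replicate 2 it was 131 and 261. It was 181, 159, 165, 187 and 155 without WT 3 h replicate 3, KO 3 h replicate 1, WT 12 h replicates 1 and 3 and KO 12 h replicate 1. These 5 libraries, left out 1 at a time, ended 8, 13, 11, 10 and 12 of the 35 named calls, with Il10, Il3 and Csf2 among those ended by each of the 5 (highest adjusted p over these 5 of 0.0744, 0.0747 and 0.0786). Leaving out WT 3 h replicates 1 and 2, KO 3 h replicates 2 and 3, WT 12 h replicate 2 and KO 12 h replicates 2 and 3 ended 7, 1, 9, 3, 11, 9 and 8. Without the trend, the filter and the replicate 2 libraries 19, 21 and 13 of the 35 were lost. Of the named calls 13, with Ccr8, Skil and Pmepa1 among them, were kept under each alternative.

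The genotype differences at 3 h and 12 h mostly went the same way for genes called at either time. Across all 12436 genes, which are not independent replicates, Pearson's r was 0.324 and Spearman's rho 0.235, and across the 188 genes called at either time r was 0.701 and rho 0.707. These differences share no library but are not independent, since WT libraries of the same number deviated alike at both times. They did so less without the sex-linked genes (0.132, 0.112 and 0.0851). When KO and WT were swapped for 1 or 2 replicate numbers at both times, a comparison chosen after seeing the data, r over all genes was 0.115, 0.0732 and 0.00681. The share of all genes with the same sign was 56.7%, and up to 59.1% when libraries were swapped within pairs in other ways. Of the 130 genes called at 3 h 118 had the same sign at 12 h, and of the 83 called at 12 h 78 had the same sign at 3 h. Both times called 18 genes higher, where independent lists of these sizes would share 0.184 (a value that leaves out the pairing), among them Skil, Pmepa1, Smad3, Ccr8, Ccl1, Bhlhe40 and Runx1, and 7 lower, where 0.157 would be shared, among them Itgb3, Cd226, Gimap7, Ms4a4b, Ms4a6b and Snx9.

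**Figure D3:**
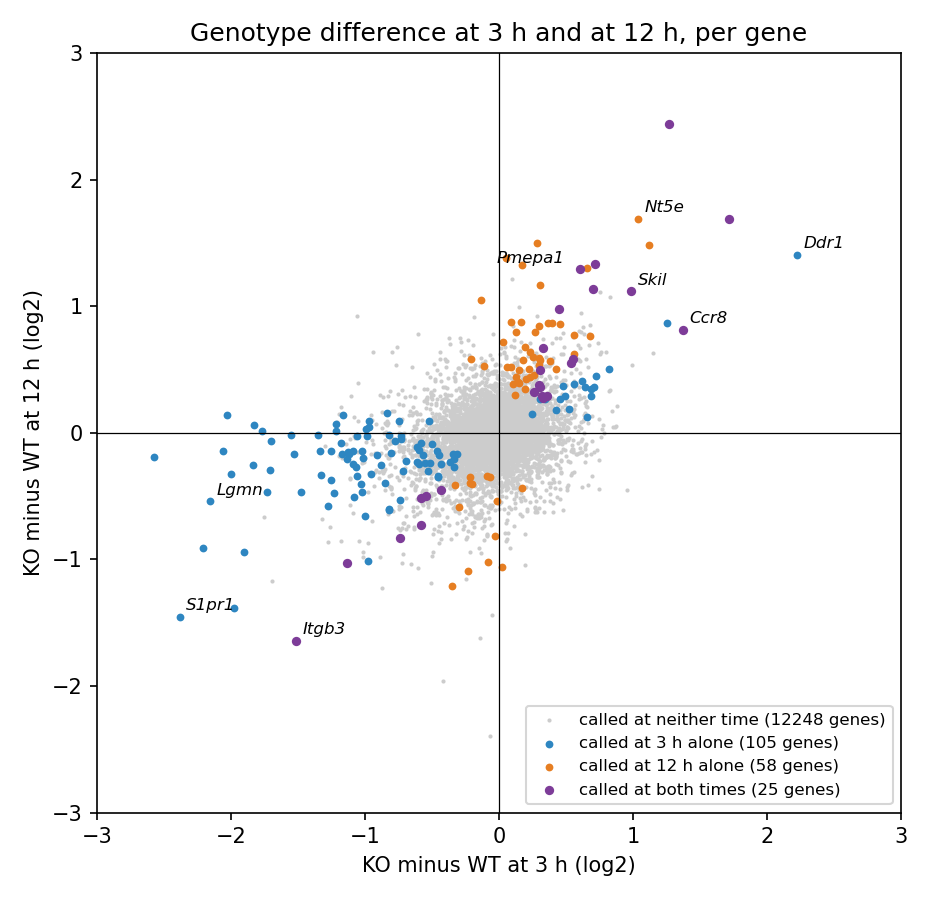
Log2 difference of KO-labelled minus WT libraries at 3 h (horizontal axis) and at 12 h (vertical axis) for each kept gene, coloured by the times at which it was called. The 25 genes called at both times lie in the quadrants of equal sign.

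Whether the genotype difference itself changed between the times was tested as an interaction. The rise of Pmepa1 was larger at 12 h by 0.69 ± 0.10 (SE), with limma adjusted p = 0.0552, the smallest of the comparison. Limma thus called 0 genes, with 497 at an unadjusted p under 0.05. With the replicate block 3 genes were called higher, though the numbers did not pair the KO-labelled libraries across times. Among them were Pmepa1 (adjusted p = 0.0438; range over its 21 alternatives 0.00625 to 0.319) and Furin, which encodes a protease that processes TGF-β and was chosen after its values were seen (0.64, adjusted p = 0.0111; 0.0111 to 0.743). The count was 0 without the trend and with array weights, 2 with robust eBayes and 2 with quantile normalization, Pmepa1 among them in both. It was 3 without the filter, all of them low genes that the filter removes, with differences of -0.148, 0.163 and -0.0869. Pmepa1 and Furin were not called there (limma adjusted p = 0.0817 and 0.743). The count was 28, 1 and 2 without WT 3 h replicate 2, WT 12 h replicate 3 and KO 12 h replicate 2. Pmepa1 was called in the first and the last of these (adjusted p = 0.0258 and 0.00625), and Furin in the first (0.0362). As a list the TH17 genes differed between the times. All 18 had a more positive difference at 12 h, with a median of 0.31 (camera adjusted p = 5.46e-11) and 5 higher when adjusted over the list alone. This was the 1 list of the comparison that held with an estimated correlation (adjusted p = 0.0104). IL-6 and STAT3 responsive genes also moved up (4.56e-07; adjusted p = 0.0865 with an estimated correlation, and 0.0493 with the replicate block as well). Of them 17 of 22 were positive, with a median of 0.15 and 4 higher when adjusted over the list alone. Cell cycle genes moved down, with a median of -0.18 (1.02e-05; adjusted p = 0.126 with an estimated correlation) and 1, Ccnd3, lower when adjusted over the list alone.

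From 3 h to 12 h most cell cycle genes rose and most type I interferon response genes fell in libraries of both labels. With an estimated correlation the cell cycle list held in WT (adjusted p = 0.0466) but not in KO-labelled libraries (0.0710), and the interferon list in neither (0.169 and 0.199). In WT, Dtl, the substrate receptor of a ubiquitin ligase that destroys the replication licensing factor CDT1 (chromosome 1, 191537356 to 191575544), rose by 5.16 ± 0.16 (35.8-fold, limma adjusted p = 7.96e-13). Kcnq5, a potassium channel, rose by 5.73 ± 0.24 (1.24e-11) and Chaf1a, a histone chaperone of replication, by 4.14 ± 0.15. Orc1, of the origin recognition complex, rose by 4.12 ± 0.22, Uhrf1, a reader of methylated DNA, by 3.96 ± 0.13, and Rpph1, the RNA of RNase P, by 3.96 ± 0.39. Iigp1, an interferon-induced GTPase (chromosome 18, 60376027 to 60392634), fell by 6.23 ± 0.33 (74.9-fold, 1.93e-10). Lower too were Rtp4, another interferon-induced gene (-6.02 ± 0.30), and Oas2 and Oas1a, sensors of double-stranded RNA (-4.99 ± 0.30 and -4.74 ± 0.35). The next were Irf7, an interferon regulatory factor (-4.94 ± 0.26), and Zbtb20, a zinc finger repressor (-4.91 ± 0.33). In KO-labelled libraries Kcnq5 rose by 5.11 ± 0.24, Dtl by 4.68 ± 0.16, Cby1 by 4.27 ± 0.33, Chaf1a by 4.18 ± 0.15, Rpph1 by 4.10 ± 0.39 and Fam129a by 3.93 ± 0.18. There the largest falls were in Iigp1 (-6.60 ± 0.33), Rtp4 (-5.98 ± 0.30), Irf7 (-5.34 ± 0.26), Oas2 (-5.26 ± 0.30), Ddx58, which encodes the RNA sensor RIG-I (-5.20 ± 0.21), and Oas1a (-5.02 ± 0.35). Limma called 8449 genes in WT (4271 higher, 4178 lower) and 8453 in KO-labelled libraries (4269 and 4184). The 12 named calls of each were kept under each alternative. After centring each library on its median, the median change over all genes was -0.109 in WT and -0.134 in KO-labelled libraries, against -0.00044 and -0.0017 before. The share of calls that were higher went from 50.6% to 42.2% and from 50.5% to 40.4%, so these changes are relative to the authors' scaling.

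By list, 31 of 37 cell cycle genes rose with time in WT and 3 fell (median 1.92; camera adjusted p = 1.04e-09; adjusted p = 0.0466 with an estimated correlation). In turn 28 rose and 3 fell in KO-labelled libraries (7.46e-09; adjusted p = 0.0710 with an estimated correlation). Type I interferon genes fell, 31 of 33 in each genotype, with 1 rise in WT and 2 in KO-labelled libraries (1.21e-10 and 1.14e-09; adjusted p = 0.169 and 0.199 with an estimated correlation; median -2.71 in WT). Early activation genes fell in 27 of 30 in each, with 2 and 3 rises (1.79e-11 and 5.48e-11; adjusted p = 0.0570 and 0.0790 with an estimated correlation). Of the oxidative phosphorylation genes 24 of 27 rose in each (2.86e-07 and 2.88e-07; adjusted p = 0.254 and 0.233 with an estimated correlation). In WT 15 of 18 TH17 genes, 20 of 22 IL-6 and STAT3 genes and 22 of 29 TGF-β and SMAD target genes fell from 3 h to 12 h, with 1, 2 and 4 rises, and each list had adjusted p = 0.0466 with an estimated correlation. For TH17 genes it was 0.0822 with the replicate block as well. In KO-labelled libraries 12, 19 and 21 fell, with 2, 2 and 4 rises, at adjusted p = 0.144, 0.0710 and 0.0710. Adjusted over the list alone, each count in this paragraph was the same.

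Of the 3 untested lists, gamma-delta T and NKT markers had 1 kept gene, Blk (-0.87 ± 0.32 at 3 h and -0.30 ± 0.32 at 12 h, adjusted p = 0.331 and 1.00), erythroid and platelet markers had 3, with 0 called between genotypes by limma at either time, and mitochondrially encoded genes had 0. Blk is also a member of the B cell list, so its value is not specific to gamma-delta T or NKT cells.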

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

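The tests of B cells, of the time course within the resting list and of mixed cells were chosen after the result was seen. The regroupings that swap libraries within pairs were added after the result was seen as well. The other counts of regrouped libraries, the test without WT 3 h replicate 1, the comparison with the change over time, the gamma-delta markers and the region around Smad4 were set before.

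Results are given here where a test of the genotype difference at 12 h against that at 3 h passed, with or without the replicate block. With the replicate block, the difference was larger at 12 h by 0.69 for Pmepa1 and 0.64 for Furin on the log2 scale. Without it neither was called (adjusted p = 0.0552 and 0.303), and the numbers did not pair the KO-labelled libraries across times. By list, camera with the preset correlation gave adjusted p = 5.46e-11 for TH17 genes, 4.56e-07 for IL-6 and STAT3 responsive genes, 1.62e-06 for cholesterol synthesis genes, 1.02e-05 for cell cycle genes, 0.00218 for TGF-β and SMAD target genes, 0.00855 for follicular helper genes, 0.00855 for naive and resting genes and 0.0492 for TH1 genes. With an estimated correlation these were 0.0104, 0.0865, 0.285, 0.126, 0.107, 0.0865, 0.7 and 0.7, so of these 8 lists the TH17 list alone held in both. Medians were 0.31, 0.15, 0.15, -0.18, 0.12, 0.00, 0.04 and 0.12 in that order. Leaving out 1 library ended the preset call for TH1 genes (0.0763 and 0.476 without WT 3 h replicates 1 and 3, 0.289 and 0.304 without KO 3 h replicates 1 and 2, 0.0563 and 0.247 without WT 12 h replicates 1 and 2, 0.407 without KO 12 h replicate 3). It did so for naive genes (0.262, 0.0578, 0.0599 and 0.131 without WT 3 h replicate 1, KO 3 h replicate 1, WT 12 h replicate 3 and KO 12 h replicate 3). It did so as well for follicular helper genes (0.0571 without KO 3 h replicate 2 and 0.10 without KO 12 h replicate 3) and for TGF-β and SMAD target genes (0.0632 without WT 3 h replicate 3).

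Regrouping the libraries bears on the counts of called genes. For the mean of both times 1 of 100 drawn regroupings within each time, the real one, gave as many genes (285, against a highest of 13 in the others), so chance can be excluded if libraries are regrouped freely. Among the 32 that swap KO with WT within a replicate number, and so part all 6 pairs, 1 gave as many, the real one, and the highest other was 5. If a number stands for the same animals at both times, 4 regroupings remain, too few for a share under 0.05 (highest other 0). At 3 h and 12 h there are 10 splits each, too few for a share under 0.05. The real counts were 130 and 83 and the highest others 0 and 1. Among the 4 splits at each time that part all 3 pairs the highest other was 0. For the change with time in WT and in KO-labelled libraries the 10 splits are likewise too few, with 8449 and 8453 against a highest other of 0. For the difference between times the real count of 0 was reached by 100 of 100 regroupings, which any regrouping must reach, so nothing follows about chance. The highest other, 285, comes from swapping the genotype labels at 1 time, which turns the mean difference into the difference between times.

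TGF-β and SMAD target genes at both times, and TH17 genes at 12 h (adjusted p = 0.235 at 3 h), were higher in the KO-labelled libraries, while the SMAD components did not hold with an estimated correlation (adjusted p = 0.202 and 0.103). Passenger DNA that acts on genes near Smad4 alone is argued against as the cause of this pattern. Of the 16 TH17 and SMAD list genes called higher, 1 lies on chromosome 18. An effect of such DNA on genes elsewhere was not tested. Still, 2.16% of the genes called in the mean of both times lay within 20 Mb of Smad4 (6 of 278: Cd226, Ctif, Malt1, Rbfa, Setbp1 and Smad7), against 0.930% of kept genes. The rule set before asked for most called genes to lie there, which the 113 kept genes of this window could not meet. More gamma-delta or NKT cells cannot be told apart from these data: the median of their markers at 12 h was -0.0612, but over 5 of 13 listed genes, 4 of which lay under the minimum mean of 3, which leaves 1 kept gene, Blk (-0.30 ± 0.32). Blk is also in the list of B cell markers. The loss of Smad4 named by the labels remains a hypothesis, and the level of Smad4 itself does not bear on it.

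Resting T cell genes were lower in the KO-labelled libraries at 3 h, with 4 of 26 called; the list was not called with an estimated correlation (adjusted p = 0.223) or in fry (0.114). The dependence on WT 3 h replicate 1 alone is argued against by the list median without it, -0.21, against -0.26 with all libraries. Whether fewer B cells account for part of it cannot be told. The B cell list had a median of -0.26 (SD over members 0.25, 0 genes called), but a list median does not give how much RNA came from B cells. Cd74, an abundant member, was at 11.23 in WT and 10.95 in KO-labelled libraries. The lowest B cell gene was at -0.87, and 7 of 26 resting genes lay below it. A KO-labelled culture further along its course as a whole, by more than the spread between libraries, is argued against. Over all genes r of the difference at 3 h with the change over time was 0.00233. The cell cycle median was 0.01 and the early activation median -0.00807, both near 0 though with the signs of such a shift. On the first principal component the 3 h libraries lay at -0.272, -0.303 and -0.291 in WT and -0.278, -0.292 and -0.294 in KO-labelled libraries. Those of 12 h lay at 0.265 to 0.308. The rule set before left this undecided, since r was not at or below 0. Within the list such a shift cannot be told apart. The list fell with time (mean -0.52, 15 of 26 lower), and r over its members was -0.207 (95% interval -0.550 to 0.196, 12 of 26 shared its sign). A genotype effect stays open.

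Replicate 2 carried Y-linked transcripts in all 4 groups although the labels state female mice. A mix of male and female cells is argued against, since Xist there was at most 0.00149 of its lowest level in the other libraries on the linear scale. Female cells in these 4 libraries, as the labels state, are argued against. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty lay at 8.61 to 12.7 in them, against 1.97 to 2.77 in the other libraries. How label and cells came to differ is unknown, and no biological explanation was tested. With the block, 19 genes differed between replicate 2 and the others (5 higher, 14 lower), among them Ddx3y by 9.91, Xist by -10.74, and Cxcr3, Ccl3, Crtam and Xcl1 by -0.57, -0.56, -0.40 and -0.71.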

How the results depend on the processing

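The alternative without the 4 replicate 2 libraries, and those that join the block with another choice, were chosen after seeing the data. The others here were planned. Between genotypes the count of called genes moved most at 3 h (130): 9 without the trend, 14 without the filter, 32 on the compared groups alone, 54 with array weights, 200 with the replicate block, and 22 to 261 with 1 library left out. The blocked count fell to 44, 59 and 73 without KO 3 h replicate 1 and WT 3 h replicates 1 and 3 (44 to 251 over all libraries left out) and was 183 with array weights. At 12 h (83) it was 39 without the trend, 40 without the filter, 167 with array weights, 22 without replicate 2, and 49 to 102 with 1 library left out. With the block it was 114, 226 with array weights as well and 50 to 143 with 1 library left out. Robust eBayes, a minimum mean of 5, quantile normalization and median centring gave 111, 121, 120 and 139 at 3 h and 85, 90, 97 and 85 at 12 h. For the mean of both times (285) it was 128, 92 and 163 without the trend, the filter and replicate 2, and 155 to 392 with 1 library left out. For the difference between times (0) it was 2 with robust eBayes, 3 without the filter (all low genes that the filter removes), 2 with quantile normalization, 3 with the replicate block and 0 to 28 with 1 library left out. Dropping the filter tests more genes and also lets genes with low values into the estimate of the prior. Dropping libraries leaves fewer samples. How far each of these, or anything else, moved the counts was not tested. Counts for the change with time moved by less than 1.5 times under each alternative run (7777 to 8520 in WT and 7934 to 8539 in KO-labelled libraries with 1 library left out).

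Of the list tests 10, 14 and 8 were called at 3 h, at 12 h and in the difference. An estimated correlation left 1, 2 and 1, fry gave 3, 3 and 1, and leaving out 1 library 6 to 12, 10 to 15 and 6 to 10. The correlation of the genotype differences at both times (0.324) was 0.383 at a minimum mean of 5, 0.276 to 0.331 with 1 library left out, 0.253 without replicate 2 and 0.701 over genes called at either time. The cause was not tested.

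No called value of a named gene reversed under the alternatives run. Uncalled values near 0 changed sign. At 3 h Smad4 was -0.0166 without replicate 2 and -0.0307 to 0.0343 with 1 library left out, and Ski was 0.00809 with array weights, 0.00913 with median centring and -0.0530 to 0.0424. Smad4 was -0.00946 to 0.0388 at 12 h and -0.00403 to 0.0285 in the mean of both times, and Ski there was -0.00979 without replicate 2 and -0.000522 to 0.0472. In the difference Smad4 was -0.00341 with median centring and -0.0121 to 0.0534, and Skil was -0.00266 without replicate 2. The replicate block changed no named call other than those given with each comparison and Gzmb, Hspa1b and Hspa1a in the mean of both times (blocked adjusted p = 0.00173, 0.0165 and 0.0195). For the KO-labelled libraries at both times the numbers did not pair the samples (0.0637, 0.368 and 0.0892, and replicates 1 and 3 did not correlate best with their own number). The block gave 8517 calls there. Read depth is unknown, so its limit could not be computed.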

Other observations

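The genes below were chosen after their values were seen, from those called at both times. Rgs3, which encodes a regulator of G-protein signalling, was higher in KO-labelled libraries by 0.70 ± 0.12 (SE, n = 3 per group) at 3 h and 1.13 ± 0.12 at 12 h (limma adjusted p = 0.0125 and 0.000119). Tnfrsf1b, a receptor for tumour necrosis factor, was higher by 0.45 ± 0.09 and 0.98 ± 0.09, and Runx1, a transcription factor of T cells, by 0.31 ± 0.06 and 0.50 ± 0.06. Ms4a4b and Ms4a6b, membrane proteins of lymphocytes, fell by 0.58 ± 0.07 and 0.43 ± 0.08 at 3 h.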
